A study of Mus musculus with 2 samples.

How the data were processed

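CTCF ChIA-PET was deposited for 2 libraries of male embryonic stem cells of the B6CASTF1/J hybrid, fragmented by sonication per the labels. The labels number them as biological replicates 1 and 2, from separate biosamples of the same donor, and give no other group. Coordinates are on mm10 per the labels, and all positions lay within the chromosomes of the reference used here (GRCm38 with GENCODE M21 genes). Reads of the CAST/EiJ genome differ from this reference, and the effect of that on alignment was not analysed here.

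Per the notes deposited with the samples, the loops were derived from filtered alignments, and the peaks and coverage from unfiltered alignments; the coverage also drew on a second file of unstated type. The aligner, the loop caller and the peak caller are not given in the sources used here. The loop lists deposited by the authors hold a whole-number PET count per pair of anchors, with a minimum of 3 and all pairs on the same chromosome. That this count is of PETs is inferred from the values and the usual content of such files, since the lists have no header. The authors' coverage track gives signal as whole-number read coverage that is not scaled to depth, so apart from the mean depth of each library, and the ratio of these means, it was compared between libraries only as correlations or as ratios within a library. Whether the second file leaves regions out of the track is not known, so a coverage of 0 may not mean that reads were absent. The authors' peak lists give for each peak a score, a fold enrichment and a −log10 p-value and −log10 q-value, with the words for no input in the peak names; the meaning of these columns is that of the usual peak format, and they served only to rank peaks within a list. Peaks and loops were derived from each library alone, per the notes deposited with the samples.

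Mitochondrial loops and peaks were set aside after the data were seen, because they held 8.84% of loop PETs in replicate 1 and 4.76% in replicate 2. All values otherwise use the loops and peaks as deposited. A peak was called shared where it overlapped a peak of the other replicate by at least 1 bp, and a loop where both anchors overlapped both anchors of a loop of the other. Baselines came from 100 seeded circular shifts per chromosome, or from 20 for loops with anchors extended by 5 kb. For loop strength, matched loops were joined into groups, and the summed PETs of each group were compared with the remaining PETs of shared loops by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment.

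A CTCF motif of 19 bp was learned from the summits of the 5000 top peaks of each replicate in 3 rounds, starting from the textbook core of the CTCF site. It occurred in 62.4% of those summit windows (50 bp either side) and was searched in the whole genome at a per-position p-value of 1e-05. Orientation was read only where all motifs of an anchor pointed the same way. Promoters were windows of 2.5 kb either side of the start of a protein-coding gene. The imprinted list and the list of X loci also hold noncoding genes, such as H19 and Xist, with windows taken in the same way. Random genes were protein-coding for every list and were not matched on chromosome. Gene lists were compared with 10000 random lists matched on deciles of the number of start sites within 250 kb, in a two-sided permutation test adjusted over 9 lists. The gene lists, the tests and most alternatives were fixed before the data were examined.

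The named genes followed a fixed rule. For each list these were up to 4 genes with the most loop PETs at the promoter (ranked by the lower of the 2 replicates per 100000 loop PETs) and the first 2 in alphabetical order with no anchor in either replicate. The rule also took the 10 shared loops with the most PETs, the 5 anchors with the most partners, and the 3 shared loops with the largest fold each way among those past an adjusted p of 0.05. Loops were named by start sites within 2.5 kb of an anchor, by the gene an anchor lies in, or else by the nearest protein-coding gene.

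The measures were tested on simulated data. With PETs drawn for the 9934 shared loops at the real rates, 9623 held PETs in both simulated libraries. Of these, the strength test called 42.4% of 99 loops changed 4-fold, 92.9% of 98 changed 8-fold and 0 of 9426 unchanged ones. With 19.9% of 242686 loops placed again, 20.0% were found as shared. Each was moved by less than the width of its anchors, so a match was certain and larger displacements were not tested. The orientation measure returned the 60.1% of convergent pairs placed among 20000 loops. Of 1000 random lists of 28 genes, 3.8% had a permutation p under 0.05.

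The alternatives covered the overlap rule, PET minimum, peak support, thinning of the deeper replicate, bin size, motif threshold, promoter window, matching of random lists and each replicate alone. Chosen after seeing the data were anchor width, promoter coverage as the matching variable, bins without a peak or without a gene, a CTCF motif or an unknown base, mitochondrial loops, the start of chromosome 11, and loops with an anchor that has no coverage (2.34% of loops in replicate 1 and 2.42% in replicate 2). With 2 replicates a mean ± SD describes the spread between 2 libraries, except for shared peaks, where the shares are directions of the same comparison. Intervals on shares cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Allele-specific contacts were not analysed here.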

Results

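CTCF-bound chromatin contacts were measured by in situ ChIA-PET in male embryonic stem cells of an F1 hybrid between the C57BL/6J and CAST/EiJ mouse strains. In this assay chromatin bound by the insulator protein CTCF is pulled down, its DNA ends are joined by proximity ligation, and each sequenced pair of joined ends (a paired-end tag, PET) records a contact. The labels name 1 group of 2 biological replicates, from 2 biosamples of the same donor, so the comparison that the design implies is replicate against replicate. Each library came with a list of loops (pairs of anchors on the same chromosome with the number of PETs that join them), a list of peaks and a track of read coverage, all on mm10. The PET number has no heading in the files and was read as such from its values and the usual content of this file type. Replicate 1 held 242686 nuclear loops carrying 1195383 PETs and 230470 nuclear peaks. Replicate 2 held 155350 loops carrying 692100 PETs and 179755 peaks. Mean nuclear coverage was 2.71 reads per reference base in replicate 1 and 1.62 in replicate 2, a ratio of 1.67. The depth behind a single loop was low: the median was 4 PETs in replicate 1 and 3 in replicate 2, and 44.7% and 50.01% of loops held the file minimum of 3 PETs. Anchors were mostly narrow, and both anchors were at most 700 bp wide in 70.1% of the loops of replicate 1 and 65.9% of those of replicate 2. For the main shares and counts, the value for the loops with both anchors over 1000 bp, here called wide-anchor loops, is given beside that for all loops. That subset was chosen after seeing the data and held 15352 loops in replicate 1 and 12893 in replicate 2. PETs at named genes count all loops and depend on that choice. Of the 33 named genes that had PETs, 16 fell by more than 1.5 times in windows of 1 kb (Pou5f1 to 1.10 ± 0.936 per 100000 loop PETs and H19 to 0.776 ± 0.742, SD, n = 2) and 7 rose by more than 1.5 times in windows of 5 kb. All 33 fell by more than 1.5 times with 10 PETs or more (median ratio 0.174) and with wide-anchor loops alone (median ratio 0.124; Gnas to 0.217 ± 0.307, SD, n = 2, and Hsp90ab1 to 0).

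The first comparison asked which contacts were found in both replicates. Overlapping loops were grouped and their PETs summed. The strongest contact present in both lists, outside regions with no read coverage, joined the promoter of Nes, which encodes the intermediate filament protein nestin of neural progenitors, to coding exons of Bcan, which encodes the brain proteoglycan brevican. It ran on chromosome 3 from 87968416 to 87989566 and carried 166 PETs in replicate 1 and 87 in replicate 2. An intron of the imprinted potassium channel gene Kcnq1 was joined to an intergenic anchor beside the promoter of Cdkn1c, an imprinted inhibitor of the cell cycle, across 310 kb of chromosome 7 (143153167 to 143469058), with 102 and 67 PETs. The anchors of this contact held convergent CTCF motifs. Foxn1, a transcription factor of thymic epithelium, was joined to the sodium transporter gene Slc13a2 on chromosome 11 (78357980 to 78402270), exon to exon and again with convergent motifs, with 88 and 82 PETs.

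The other contacts among the 10 with the most PETs in both replicates were mostly short and lay in or near genes. The germ-cell gene Ybx2 was joined to Slc2a4, which encodes the insulin-responsive glucose transporter, on chromosome 11 (69930347 to 69952885; 90 and 79 PETs). A coding exon of the tetraspanin gene Cd82 was joined to an intergenic anchor 51.2 kb away on chromosome 2 (93414543 to 93471866; 113 and 59 PETs). The Rhof promoter region was joined to coding exons of Setd1b, a histone methyltransferase gene, on chromosome 5 (123131625 to 123152058; 87 and 65 PETs). Ndufa4l2 was joined to the end of Lrp1 that lies beside the Nxph4 promoter on chromosome 10 (127511676 to 127538969; 106 and 50 PETs). An intergenic pair between Rbfox2 and Apol7a on chromosome 15 (77335091 to 77362622) had 86 and 63 PETs. The contact with the most PETs of all joined coding exons of Sfi1 on chromosome 11 to an anchor near the start sites of Sfi1 and Eif4enif1 that reached into Drg1 (3156299 to 3200269; 308 and 626 PETs). A contact between Lzts2 and Pdzd7 on chromosome 19 (45009792 to 45034021) had 109 and 104 PETs. Both anchors of these last 2 contacts, and the right anchor of the chromosome 15 pair, had no reads in the coverage track of either replicate. Whether the track leaves such regions out is not known, so its 0 there may not mean that reads were absent.

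**Figure D1:**
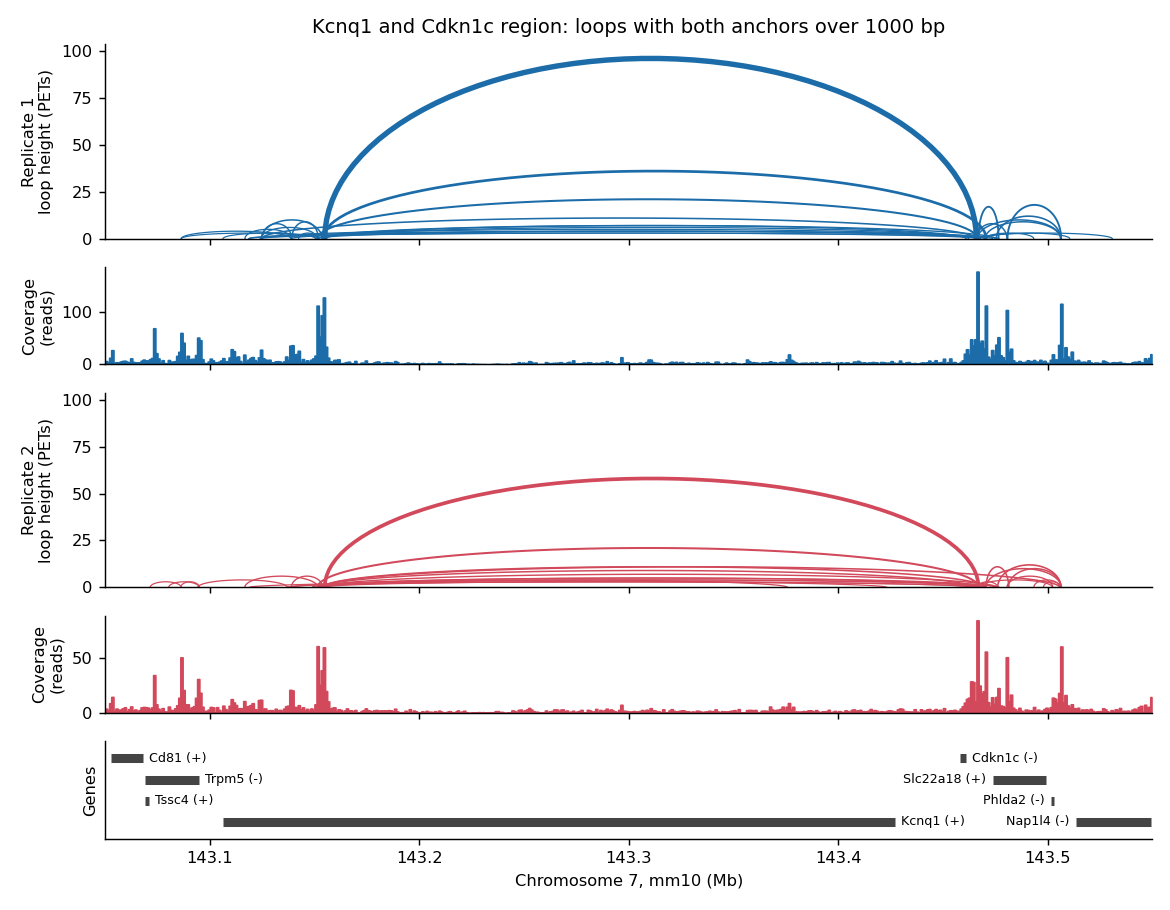
The Kcnq1 and Cdkn1c region of chromosome 7 in both replicates: arcs join the midpoints of wide-anchor loops with a height equal to their PETs, filled tracks give mean read coverage in bins of 1 kb, and bars give protein-coding genes with their strand against position in Mb. The tallest arc reaches 96 PETs in replicate 1 and 58 in replicate 2 and ends beside Cdkn1c in both.

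Most listed loops had no counterpart in the other replicate. Of the loops of replicate 1, 10830 (4.46%, 95% exact binomial interval 4.38 to 4.55) had a loop in replicate 2 with both anchors overlapping, and of the loops of replicate 2, 10655 (6.86%, 6.73 to 6.99) had a counterpart in replicate 1. Shifting the other replicate along its chromosomes 100 times left a mean of 0.0719% and 0.110%. The shared part rose with PETs, from 2.84% of loops with 3 PETs to 36.9% (34.3 to 39.6) of those with 20 or more in replicate 1, and from 5.13% to 44.8% (39.5 to 50.3) in replicate 2. It fell with distance: among loops under 20 kb 12.3% and 16.6% were shared, against 3.05% and 4.81% at 100 to 500 kb and 0.0120% and 0.0284% beyond 2 Mb. Wide-anchor loops were shared in 30.5% and 36.6% of cases, and in 85.6% (82.4 to 88.4) and 95.2% (90.4 to 98.1) with 20 PETs or more. Loops with both anchors at most 700 bp were shared in 0.653% and 0.830% of cases, and in 1.10% (0.407 to 2.39) and 3.94% (1.29 to 8.95) with 20 PETs or more. Narrow anchors have less room to overlap: shifts left a mean of 0.0379% and 0.0508% of these loops, against 0.286% and 0.402% of wide-anchor loops. With anchors extended by 5 kb on each side 26.5% and 33.1% of loops were shared, against 5.56% and 7.69% after shifts. These intervals cover counting error only, since PETs have no molecular identifiers in these files.

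**Figure D2:**
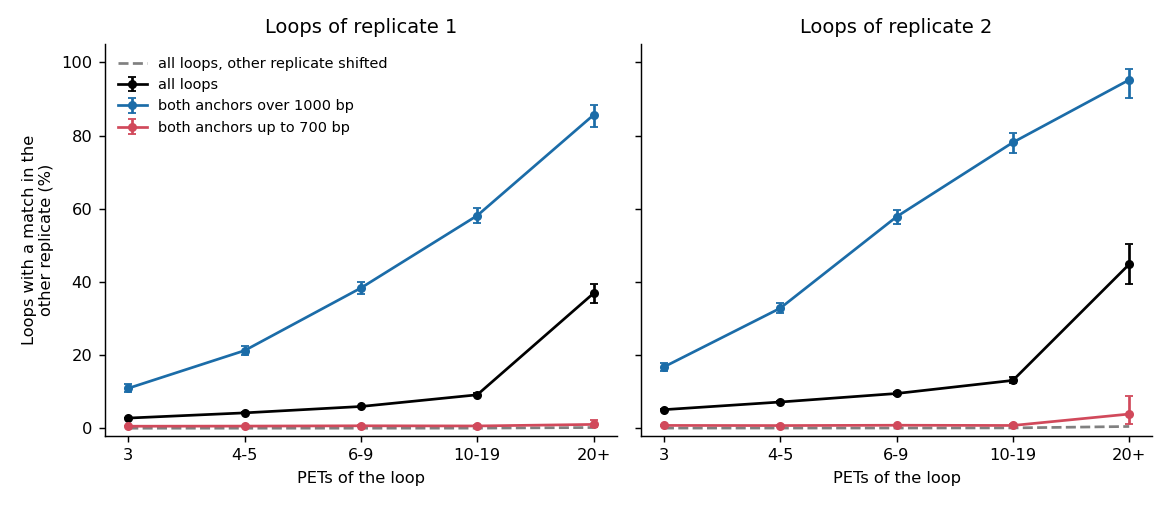
Percent of loops of each replicate with a match in the other, by PETs of the loop, for all loops (black), for loops with both anchors over 1000 bp (blue) and for loops with both anchors up to 700 bp (red), with 95% exact binomial intervals; the dashed line is the mean of 100 circular shifts. In the class of 20 PETs or more, 85.6% and 95.2% of the blue class were matched in replicates 1 and 2, against 1.10% and 3.94% of the red class.

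Peaks and coverage were shared more widely than loops. Of the peaks of replicate 1, 45.1% overlapped a peak of replicate 2 by at least 1 bp, against 5.19% after circular shifts. Of the peaks of replicate 2, 59.9% overlapped a peak of replicate 1, against 6.69% after circular shifts. The 2 shares are directions of 1 comparison, so their mean of 52.5% ± 10.5 (SD) gives no spread over replicates. In the highest quintile of each list by the authors' fold enrichment 84.9% and 91.4% were shared, and in the lowest quintile 25.3% and 43.4%. The highest quintile held a CTCF motif in 55.8% and 61.8% of peaks, and the lowest in 7.31% and 7.06%. Promoters of protein-coding genes (2.5 kb either side of the start site) took up 10.9% and 11.7% of peaks. Across 272543 bins of 10 kb, log2 coverage correlated between the replicates with Pearson r = 0.981 and Spearman rho = 0.969; bins are not independent replicates and no p-value was attached.

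Of 9934 contacts shared by the 2 libraries, 75 differed in strength by the exact test. An intergenic site beside Pecam1, which encodes an endothelial adhesion molecule, was joined to a Pecam1 intron on chromosome 11 (106647734 to 106743761) by 61 PETs in replicate 1 and 3 in replicate 2. That is 15.6-fold (95% interval 5.08 to 77.6) higher in replicate 1 relative to all PETs of shared loops (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 2.57e-08). Contacts between intergenic anchors beside Cblc and Ceacam19 on chromosome 7 (19800420 to 19874006; 48 and 3 PETs, 12.2-fold, adjusted p = 7.47e-06 by Fisher's exact test) and between intergenic anchors beside Ift27 and Ncf4 on chromosome 15 (78178039 to 78240293; 40 and 3 PETs, 10.2-fold, adjusted p = 0.000187 by Fisher's exact test) were higher in the same replicate. In the other direction, an intergenic pair between Neurog1, a neuronal determination factor, and the chemokine gene Cxcl14 on chromosome 13 (56265424 to 56280326) had 3 and 29 PETs, 12.6-fold higher in replicate 2 (adjusted p = 4.58e-05 by Fisher's exact test). Gpr84 was joined to Zfp385a on chromosome 15 (103305465 to 103325827), and the ephrin gene Efna3 to Adam15 beside the Efna4 promoter on chromosome 3 (89316587 to 89340578), each with 3 and 22 PETs (9.58-fold, adjusted p = 0.00264 by Fisher's exact test). In each contact named in this paragraph the weaker library stood at 3 PETs, the minimum of the lists.

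Of the 75, 34 were higher in replicate 1 and 41 in replicate 2. Of 2518 wide-anchor contacts 52 passed, 25 higher in replicate 1 and 27 in replicate 2. Across all shared contacts the PETs correlated with Spearman rho = 0.354, and across wide-anchor contacts with 0.464. Among the 1500 contacts with summed PETs of 20 or more, 223 passed, 163 higher in replicate 1 and 60 in replicate 2, and rho was -0.0046. These contacts were picked on the sum of the PETs compared, which by construction lowers rho and favours unequal contacts. The sum was not scaled to depth, which favours the deeper replicate 1. These values therefore do not show how well strong contacts match between replicates. The Sfi1 contact was among the 75, 2.66-fold higher in replicate 2 (adjusted p = 3.05e-44 by Fisher's exact test), and all 8 contacts called in the surrounding 150 kb of chromosome 11 were higher in that replicate. The Nes contact (adjusted p = 0.212), the Kcnq1 contact (adjusted p = 1) and the Foxn1 contact (adjusted p = 1) did not pass the same exact test. With summed PETs of 20 or more the Nes contact passed (adjusted p = 0.0371 by the exact test), and with mitochondrial loops in the scaling the Foxn1 contact passed, higher in replicate 2 (adjusted p = 0.00376 by the exact test). Scaling by the PETs of all loops instead of shared loops gave 101 calls, 16 higher in replicate 1 and 85 in replicate 2, and including the mitochondrial loops in the scaling gave 220, 10 and 210. With anchors extended by 5 kb, which merges neighbouring loops, the Pecam1, Ift27, Gpr84 and Efna3 contacts no longer passed (Pecam1: 110 and 55 PETs, adjusted p = 0.376 by the exact test), although 942 contacts then did. The Cblc contact (295 and 141 PETs) and the Neurog1 contact (36 and 54 PETs) still passed, at log2 ratios of replicate 1 to 2 of 0.53 and -1.12, against 3.61 and -3.66 without extension. The test compares 2 libraries, not conditions, and its p-values and fold intervals treat PETs as independent molecules and cover counting error only.

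Contacts spanned a median of 148.9 kb in replicate 1 (quartiles 38.9 and 674.5 kb) and 134.0 kb in replicate 2 (33.7 and 589.5 kb), a mean of 141.4 kb ± 10.6 (SD, n = 2). Wide-anchor loops were shorter, with medians of 33.5 and 27.2 kb (mean 30.3 kb ± 4.46, SD, n = 2), and 0.0586% and 0.0310% of them were longer than 2 Mb. Of the loops with both anchors at most 700 bp, 22.5% and 21.4% were longer than 2 Mb.

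The orientation of CTCF motifs at paired anchors was examined because CTCF loops classically join motifs that point towards each other. Among loops whose anchors each held motifs of 1 orientation, 40.1% of 18094 in replicate 1 (95% exact interval 39.4 to 40.9) and 40.6% of 10483 in replicate 2 (39.7 to 41.6) were convergent, 43.8% and 43.4% tandem, and 16.1% and 16.0% divergent. Random orientation gives 25% convergent (two-sided exact binomial test, p = 3.53e-269 in replicate 2 and smaller in replicate 1). The test and the intervals treat loops as independent, although loops can share anchors and motifs, so these p-values are too small. The convergent part rose with PETs, from 36.1% and 36.9% at 3 PETs to 71.0% (65.3 to 76.3) and 72.5% (58.3 to 84.1) at 20 or more. It was highest in loops of 100 to 500 kb, at 49.7% and 51.6%, and was 27.4% and 27.2% under 20 kb. Beyond 2 Mb it was 23.2% and 23.8%, which could not be told from 25% (exact binomial p = 0.186 and 0.578). Wide-anchor loops were convergent in 50.6% and 48.5% of cases, and in 76.2% and 78.0% with 20 PETs or more, whereas loops with both anchors at most 700 bp were convergent in 28.01% (26.8 to 29.3) and 27.6% (25.8 to 29.5).

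**Figure D3:**
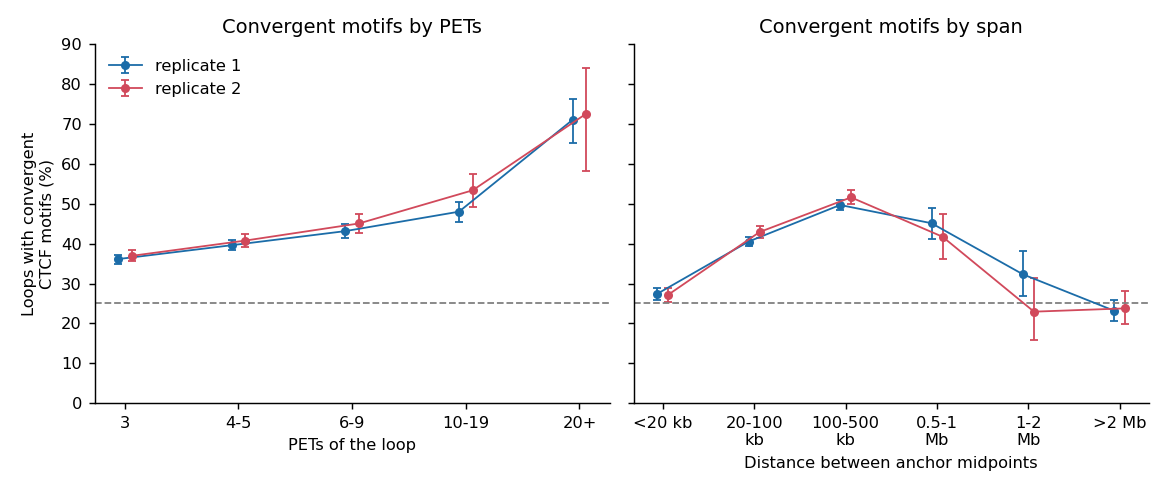
Percent of loops with convergent CTCF motifs by PETs (left) and by distance between anchor midpoints (right) in replicate 1 (blue) and replicate 2 (red), with 95% exact binomial intervals; the dashed line marks 25%, the value for random orientation. The convergent part reaches 71.0% and 72.5% at 20 PETs or more, and in the span classes is highest at 100 to 500 kb.

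CTCF peaks lay at loop anchors in 51.3% (95% exact interval 51.1 to 51.5) of cases in replicate 1 and 44.2% (44.0 to 44.5) in replicate 2. The highest quintile of peaks by the authors' fold enrichment lay at anchors in 72.1% and 64.4% of cases, the lowest in 48.0% and 41.7%, and the next quintiles above the lowest in fewer, 42.7% and 34.5% for the second and 42.7% and 36.4% for the third. In turn, 56.9% and 47.8% of anchors held a peak of their own library, and 34.1% and 24.4% of loops had a peak in both anchors. For wide-anchor loops these values were 88.9% and 81.2% of anchors and 78.8% and 64.6% of loops, but only 8.92% and 9.54% of peaks lay at their anchors.

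Promoters of genes that maintain pluripotency were frequent at loop anchors. Of 28 listed pluripotency genes, 24 (85.7%) had an anchor within 2.5 kb of the start site in both replicates, against 48.7% of random genes of equal local gene density (two-sided permutation test over 9 lists, adjusted p = 0.0009). Pou5f1, which encodes the core pluripotency factor OCT4 (chromosome 17, start site 35506018), had 4.11 ± 0.0969 loop PETs per 100000 (SD, n = 2), the growth factor gene Fgf4 (chromosome 7, 144847367) 5.42 ± 2.15, the transcription factor gene Tbx3 (chromosome 5, 119670669) 3.83 ± 0.0967 and the NODAL co-receptor gene Tdgf1 (chromosome 9, 110946158) 4.29 ± 1.09. The list did not pass against random genes of equal promoter coverage, a match chosen after seeing the data (78.5%, permutation test, adjusted p = 0.986), or with 10 PETs or more (adjusted p = 1). Promoter coverage comes from the same libraries as the loops. Matching on it can remove an enrichment whatever its source, so that comparison does not explain the enrichment.

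Genes that pattern the embryo lay above random genes of equal gene density too, though less firmly. Of 39 Hox genes, 31 (79.5%) were anchored in both replicates against 57.8% of random genes (permutation test, adjusted p = 0.0162). The list did not pass in windows of 1 kb (permutation test, adjusted p = 0.0832), among wide-anchor loops (1) or at equal promoter coverage (0.986), where the last 2 differences were below 0. The 39 genes form 4 loci. With loci counted the list did not pass either (permutation test, adjusted p = 0.262), but 4 loci could not pass even if all were anchored. Hoxc8 (chromosome 15, 102990607) had 10.2 ± 4.62 PETs per 100000 (SD, n = 2), Hoxb5 (chromosome 11) 4.34 ± 0.812, Hoxa7 (chromosome 6) 3.84 ± 0.124 and Hoxa10 (chromosome 6) 3.48 ± 0.188. Of 34 developmental regulators, 24 (70.6%) were anchored against 46.3% (permutation test, adjusted p = 0.0171). This list did not pass in windows of 1 kb (permutation test, adjusted p = 0.0540), with 10 PETs or more (0.837), without matching on gene density (0.131), in replicate 2 alone (0.0963), among wide-anchor loops (0.312) or at equal promoter coverage (1), where its difference was below 0. The neurogenic factor gene Neurog2 (chromosome 3, 127633135) had 9.19 ± 0.732 PETs per 100000 (SD, n = 2), the mesendoderm factor gene Eomes (chromosome 9) 5.06 ± 1.84, the signalling gene Wnt1 (chromosome 15) 4.81 ± 2.19 and Sox1 (chromosome 8) 2.81 ± 0.312. Runx1, a regulator of blood formation, had no anchor in either replicate.

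Olfactory receptor genes lay at the other end. Of 1135 such genes, 60 (5.29%) were anchored in both replicates, against 60.6% of random genes of equal gene density (permutation test, adjusted p = 0.0009; the unadjusted 0.0002 is the smallest that 10000 random lists allow). Olfr71 and Olfr156 on chromosome 4, Olfr94 on chromosome 17 and Olfr718-ps1 on chromosome 5 were the exceptions with the most PETs (5.76 ± 1.199 per 100000 at Olfr71, SD, n = 2), and Olfr1 and Olfr1000 had no anchor. Among wide-anchor loops 2 of the 1135 were anchored (0.176% against 13.5%, permutation test, adjusted p = 0.0018).

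The remaining 5 lists did not pass the permutation test. Imprinted genes were anchored in 25 of 39 cases (64.1% against 49.3%, permutation test, adjusted p = 0.126), led by Phlda2 (chromosome 7, 11.7 ± 5.47 PETs per 100000, SD, n = 2), H13 (chromosome 2, 9.64 ± 1.69), Gnas (chromosome 2, 7.56 ± 0.753) and H19 (chromosome 7, 142578143, 7.55 ± 0.973), while Grb10 and Igf2r had no anchor. Restricted to wide-anchor loops, 8 of the 39 were anchored against 5.55% of random genes (permutation test, adjusted p = 0.0072), and the list also passed in windows of 5 kb (permutation test, adjusted p = 0.00468) and with 10 PETs or more (0.0225). Among those 8, Peg3 and Usp29 share a promoter and its loops. The list did not pass in windows of 1 kb (35.9% against 34.7%, permutation test, adjusted p = 0.999), with loci counted (0.130), at equal promoter coverage (61.1% of random genes, 0.986), without matching on gene density (0.284) or in either replicate alone (0.108 and 0.461). Genes of the CTCF and cohesin machinery were anchored in 14 of 20 cases (70.0% against 52.4%, permutation test, adjusted p = 0.217). Nipbl, which encodes the cohesin loader, had 3.92 ± 0.581 PETs per 100000, Pds5b 4.13 ± 1.14, Smc3 3.52 ± 0.694 and Top2a 2.502 ± 0.344 (SD, n = 2). Rad21 and Pds5a had no anchor. Housekeeping genes were anchored in 16 of 20 cases (80.0% against 58.4%, permutation test, adjusted p = 0.126), with 5.59 ± 0.140 PETs per 100000 at Hsp90ab1, 3.095 ± 0.118 at Rplp0, 2.94 ± 0.134 at Eef2 and 2.79 ± 0.672 at Tubb5 (SD, n = 2). These shares were near those of the Hox list (79.5% against 57.8%), which passed with 39 genes. That the 20 housekeeping genes did not pass is therefore no sign that they lie at anchors less often than Hox genes. Markers of other cell types were anchored in 11 of 23 cases (47.8% against 54.2%, permutation test, adjusted p = 0.685), among them Apoa1, Ckm, Krt14 and Afp but not Alb or Cd8a. Of the 6 X inactivation centre and X repeat loci only 4933407K13Rik had an anchor in both replicates (permutation test, adjusted p = 0.361).

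Promoter coverage, read from the same libraries as the loops, also differed between the lists. Relative to the library mean, median coverage of the promoter window was 3.37 at pluripotency genes, 3.23 at Hox genes and 2.53 at developmental regulators, against 1.82 over all protein-coding genes and 0.257 at olfactory receptors. At the lists that did not pass it was 2.88 (CTCF and cohesin machinery), 2.07 (housekeeping), 1.83 (imprinted), 1.29 (X loci) and 0.983 (markers of other cell types). Random lists matched on promoter coverage had means of 82.4% for the Hox list and 72.1% for the developmental list, and olfactory receptors stayed below theirs (9.79% of random genes, permutation test, adjusted p = 0.0018). The match was by classes of coverage, within which coverage can still differ. It therefore does not show that olfactory receptors lie lower at strictly equal coverage. Among wide-anchor loops 7 of 28 pluripotency genes were anchored, and that list passed (permutation test, adjusted p = 0.0072).

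**Figure D4:**
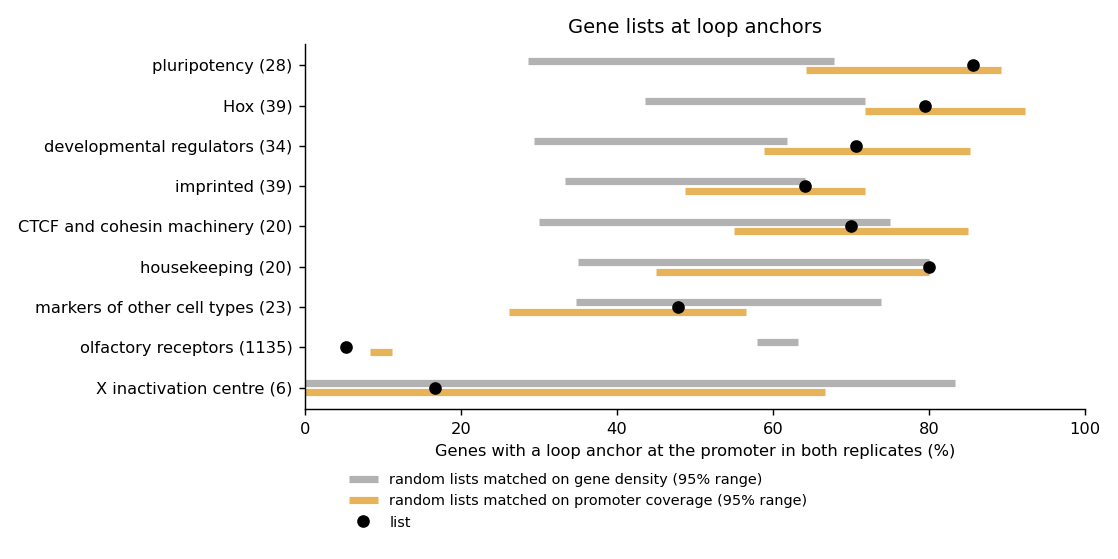
Percent of genes of each list (number of genes in brackets) with a loop anchor within 2.5 kb of the start site in both replicates (black points), with the 95% range of 10000 random lists matched on gene density (grey bars) or on promoter coverage (orange bars). The pluripotency point, at 85.7%, lies above its grey bar and inside its orange bar, and the olfactory receptor point, at 5.29%, lies below both of its bars.

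Over all 21938 protein-coding genes, 70.4% of promoters overlapped a loop anchor in replicate 1, 61.7% in replicate 2 and 53.8% in both. Circular shifts of the anchors gave 40.3%, 33.6% and 22.4%. Wide-anchor loops reached 8.597% of promoters in both replicates.

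Anchors with many partners were ranked by the lower of the 2 replicates, which favours sites found in both. The first by this rank covered the neighbouring promoters of Pip5k1c, a phosphoinositide kinase gene, and Tjp3, a tight junction gene, on chromosome 10 (81287398 to 81294670), with 50 partner anchors in replicate 1 and 46 in replicate 2. A site in coding exons of Clip2 on chromosome 5 (134488910 to 134495027) had 35 and 34 partners, a site in Plaur, the urokinase receptor gene, on chromosome 7 (24471469 to 24475443) 36 and 34, and a site in Tmprss9 on chromosome 10 (80878402 to 80885089) 43 and 33. An intergenic site on chromosome 3 (52843564 to 52844836), 137.7 kb from Cog6, had 34 and 33. The typical merged anchor had 1 partner, the 95th percentile was 5 and 4, and the maximum was 66 and 46, or 19 and 18 among wide-anchor loops. The anchor with 66 partners in replicate 1, looked up after that value was seen, lay in coding exons of Fbxo2 on chromosome 4 (148164735 to 148172968) and overlapped an anchor with 23 partners in replicate 2.

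The X chromosome was compared with the autosomes because the labels give the cells as male. Mean coverage of X was 0.697 reads per base in replicate 1 and 0.446 in replicate 2, or 0.245 ± 0.0122 (SD, n = 2) of that of the autosomes. In bins of 10 kb without a peak, a measure chosen after seeing the data, the median of X was 0.420 ± 0.0117 (SD, n = 2) of that of the autosomes, but low coverage itself leaves bins without a peak. In bins without a gene, a CTCF motif or an unknown base, also chosen after seeing the data, it was 0.357 in replicate 1 and 0.359 in replicate 2. X carried 23.5 and 18.9 peaks per Mb against 94.5 and 73.7 on the autosomes, and 16.2 and 11.2 loops per Mb against 100.2 and 64.1. Chromosome 11 had the highest mean coverage of the nuclear chromosomes, 4.59 and 2.65 reads per base, and the Y chromosome, much of which is repeated sequence, held 0.00825 and 0.00564.

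**Figure D5:**
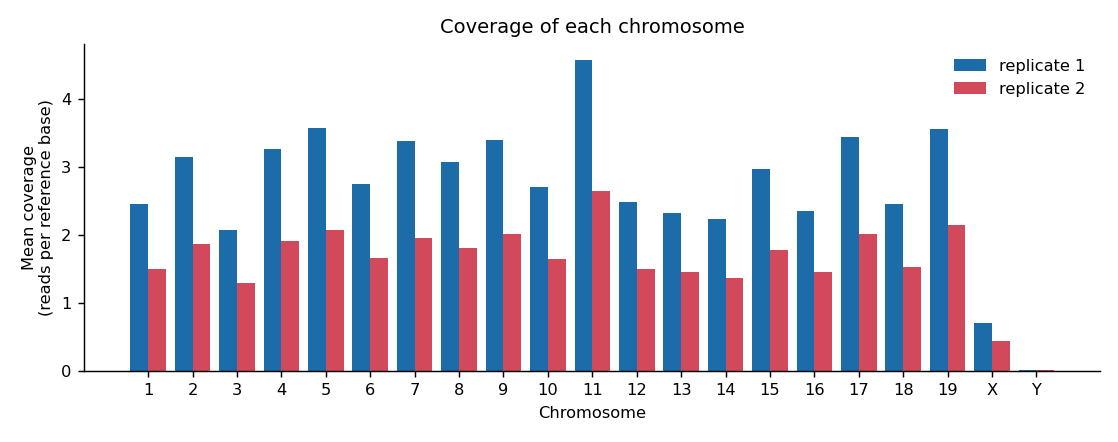
Mean read coverage of each chromosome in reads per reference base in replicate 1 (blue) and replicate 2 (red). X stands at 0.697 and 0.446, below every autosome, and chromosome 11 is highest among those drawn at 4.59 and 2.65.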

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

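The tests of this part on motif orientation, on sharing at 20 PETs or more, on the covered share of X, on X bins without a peak, on bins without a gene or CTCF motif, and the bound corrected for the choice of chromosome 11 were chosen after the result was seen; those on read starts, gene density and chromosome 11 bins without a peak were set before they were run, although chromosome 11 itself was noticed in the data.

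Mitochondrial loops were set aside from the main comparisons and entered only an alternative scaling of loop strength. They stood out because of their PETs, which summed to 115879 in replicate 1 over 2 loops and to 34583 in replicate 2 over 1 loop. No control library was compared with them, and no explanation was tested.

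Loops with both anchors at most 700 bp made up most of each list but were seldom shared between replicates, whatever their PETs. A match needs both anchors to overlap, which is harder for narrow anchors. How much of the contrast with wide-anchor loops comes from this rule was not tested, since sharing with extended anchors was not split by width. Sharply placed CTCF sites are argued against by motif orientation, but only for loops where it could be read. These were 5126 of 170129 narrow-anchor loops in replicate 1 and 2256 of 102414 in replicate 2. Among wide-anchor loops they were 4649 of 15352 and 3488 of 12893. Of the loops read, at most 28.01% of narrow-anchor loops were convergent in either replicate against 50.6% and 48.5% of wide-anchor loops. Too few counted PETs are argued against because 1.10% of narrow-anchor loops with 20 PETs or more in replicate 1 were shared. If PETs are copies of fewer molecules, however, too few molecules stay open. Copies of 1 ligated fragment counted as several PETs stay open as a candidate explanation: among narrow-anchor loops of 10 PETs or more, 54.5% in replicate 1 and 73.2% in replicate 2 had fewer distinct read starts in the coverage of an anchor than PETs, against 4.58% and 4.995% of wide-anchor loops, although a narrower anchor also has fewer bases in which other reads can start. The design names no group that gives a biological explanation, so none was tested.

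Coverage of X lay far below 0.5 of that of the autosomes. Fewer covered bases do not account for it alone, since the covered share of X was 0.437 of that of the autosomes, well above the ratio of depths of 0.245. A single copy at the gene density of X does not account for it alone either. X depth was 0.603 of the value expected from those 2, below the 95% prediction interval from the 19 autosomes in both replicates. That fit assumes a single copy and leaves out the covered share. Gene density together with fewer covered bases was therefore not tested and stays open. A single X per cell, which the labels imply, stays open: bins without a peak (0.420) are chosen by coverage itself and decide nothing, and in bins without a gene or CTCF motif X stood at 0.358 of the autosomes, between the bounds set for either answer. What lowers X in the other bins was not tested.

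Chromosome 11 had the highest mean coverage of the nuclear chromosomes in both replicates. Gene density stays open, although depth was 1.21 times the value predicted from the other 18 autosomes and just above the 95% prediction interval in each replicate (4.59 against 4.55, and 2.65 against 2.61), because that bound was wrong for a chromosome picked as the highest of 19 and was 5.08 and 2.90 when corrected for that choice. An extra copy in most cells stays open too: the 1.11 times the predicted value in bins without a peak rests on a choice of bins that coverage decides, and in bins without a gene or CTCF motif the ratio was 1.02. The intervals around that prediction, 0.604 to 0.938 in replicate 1 and 0.477 to 0.701 in replicate 2, are too wide to exclude the smallest gain set for this test. Larger gains, such as an extra copy in every cell, were not weighed against them. In these bins another autosome stood above chromosome 11 (0.838 against 0.777 in replicate 1 and 0.636 against 0.602 in replicate 2). No biological explanation was tested.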

How the results depend on the processing

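Alternatives by anchor width, promoter coverage, the choice of X bins, anchors with no coverage, mitochondrial loops and the start of chromosome 11 were chosen after seeing the data. Convergent orientation kept its direction and side of the threshold under every alternative run (40.1% to 53.1%). In all 4 of its alternatives the mean share of peaks moved by less than the SD between its directions, which is no spread over replicates. The cause of each change below was not tested, except that extending anchors or changing windows or minimums alters what is counted by construction. Low PET counts limit single loops, and gene lists of 6 to 39 genes can show only large differences.

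The mean share of loops in common moved from 5.66% to 29.8% with anchors extended by 5 kb, to 15.03% with a peak in both anchors and to 18.99% for wide-anchor loops. Differing contacts went from 75 to 942 with extended anchors, 223 of 1500 with summed PETs of 20 or more and 220 with mitochondrial loops. Median span moved to 87.7 kb with a peak in both anchors and 30.3 kb for wide-anchor loops, and was 134.0 to 148.9 kb by replicate. The log2 correlation of coverage was 0.994 at 50 kb, 0.894 at 1 kb, 0.981 without the top bins and 0.978 with a pseudocount of 0.1. The X ratio was 0.420 in bins without a peak, 0.358 in bins without a gene or CTCF motif, and 0.237 to 0.254 by replicate. Peaks at anchors went from 47.8% to 7.84% at 10 PETs or more, 42.0% by peak centre and 9.23% for wide-anchor loops. Promoters in both replicates went from 53.8% to 39.3% at 1 kb, 66.6% at 5 kb, 3.50% at 10 PETs or more and 8.597% for wide-anchor loops, and single replicates gave 61.7% to 70.4%. Lists past the threshold went from 4 to 2 at 1 kb and 1 under matching on promoter coverage, and were 3 to 4 by replicate. The highest number of partners went from 56 to 33.5 at 5 PETs or more, 14.5 at 10 or more and 18.5 for wide-anchor loops.

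Some differences changed sign, among them those of the Hox and developmental lists, which had passed. Differences from random, in percentage points, were -0.186 for Hox, -2.55 for CTCF and cohesin machinery, -1.58 for housekeeping and 3.92 for other cell types among wide-anchor loops. Under matching on promoter coverage they were -2.89 for Hox, -1.47 for developmental regulators and 6.24 for other cell types, and for the X loci they ran from -5.125 to 1.3 by replicate. The log2 ratio of replicate 1 to 2 became 0.33 (chromosome 19, adjusted p = 0.0186 by Fisher's exact test), -0.10 (chromosome 7) and 0.013 (Foxn1) with extended anchors, and -0.18 (chromosome 7), -0.37 (chromosome 5) and -0.34 (chromosome 15) when scaled by all loops. For wide-anchor loops it was -0.029 (chromosome 5) and -0.031 (chromosome 15), and with mitochondrial loops -0.11 (Nes and Cd82), -0.44 (Kcnq1), -0.62 (Rhof) and -0.60 (chromosome 15). PETs at named genes moved by more than the replicate spread in 110 of 168 cases. No paired analysis was possible because there is 1 group.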

Other observations

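Other gene families, picked after the fixed lists had been seen, were compared with random genes of equal gene density, with each direction written down before its test; the comparison matched on promoter coverage and that with each locus counted once were chosen after the first result was seen. Protocadherin cluster genes, which encode neuronal adhesion proteins, were anchored in both replicates in 53 of 57 cases (93.0% against 65.0%, permutation test, adjusted p = 0.0005), and 45.6% remained anchored among wide-anchor loops against 18.3% of random genes. Their promoters had a median coverage of 7.24 times the library mean, and against random genes of equal coverage (95.5%) they did not pass (permutation test, adjusted p = 0.583). That coverage comes from the same libraries as the loops, so this comparison does not explain the difference. The 57 genes form 3 loci. With loci counted they did not pass (permutation test, adjusted p = 0.560), but 3 loci could not pass even if all were anchored. Vomeronasal receptor genes, the pheromone receptors, were anchored in 5 of 327 cases (1.53% against 54.6%, permutation test, adjusted p = 0.0005). They stayed lower against genes of equal coverage (6.71%, permutation test, adjusted p = 0.001) and over their 104 loci (permutation test, adjusted p = 0.001). For these families equal coverage means the same decile of promoter coverage. Coverage can still differ within a decile, so these comparisons do not remove all differences in coverage.

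The other predictions failed. Replication-dependent histone genes, predicted above random genes, were below them, with 27 of 67 anchored (40.3% against 63.8%, permutation test, adjusted p = 0.0013). The 67 genes form 7 loci, and they did not pass with loci counted (permutation test, adjusted p = 0.560) or at equal coverage (43.5%, adjusted p = 0.583). Ribosomal protein genes were anchored in 62.7% of 83 cases, inside the range of random lists (45.8% to 66.3%), and below random genes of equal coverage (74.4%, permutation test, adjusted p = 0.013). Zinc finger genes named Zfp plus a number were anchored in 53.2% of 365 cases, inside the range of 50.4% to 60.5%, but among wide-anchor loops in 4.66% against 9.46% (permutation test, unadjusted p = 0.001). Histone genes were also lower among wide-anchor loops (4.48% against 16.99%, permutation test, unadjusted p = 0.0036).

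The Sfi1 locus at the start of chromosome 11 held the strongest nuclear contact but no reads in either coverage track, which may leave such regions out, so whether these cells carry more copies of it than the reference was not decided by the coverage.

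Genes of the short arm of Y carried reads, although the chromosome mean was near 0; these genes were chosen after that mean was seen. Coverage of the gene body was 0.659 and 0.504 reads per base in replicates 1 and 2 at Uty, against 0.747 and 0.666 at its X homologue Kdm6a. At Kdm5d it was 0.144 and 0.134, against 4.58 and 2.47 at Kdm5c, at Eif2s3y 0.300 and 0.316, against 4.07 and 2.55 at Eif2s3x, and at Ddx3y 0.0899 and 0.222, against 0.754 and 1.11 at Ddx3x.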
